A study of Homo sapiens with 3 samples.

How the data were processed

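One series of 3 samples was analysed, all repeats of the established human breast cancer line ZR-75. Per the labels' protocols, cells were grown at 37 °C and 10% CO2 in DMEM with 5% foetal bovine serum, and RNA was taken with TRI-Reagent. Per the labels, 2 µg of RNA went into a 20 µl reverse transcription, and each 10 µl SYBR Green reaction held 1 µl of cDNA. The PCR ran for 40 cycles with 60 s at 65 °C and a melting curve, per the labels. How the threshold for Ct was set, the software, and primer efficiencies were not given in the sources used here.

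The authors deposited a Ct table (cycles, a log2 scale on which lower means more transcript) for 179 targets, ACTB included, and a normalized table of the same targets. The scale of the deposited normalized values is not given in the sources used here; they were read as percent of ACTB because ACTB is listed at 100 in one column and near it in the others. Both tables mark some targets ND, which they do not define. The deposited percent values did not match those computed from the deposited Ct values. All 486 values of the deposited normalized table were whole hundredths of a cycle on the log2 scale within a tolerance of 1e-05, so they too have the form of Ct differences. The columns are lettered A, B and C and the samples numbered, and letters were not matched to numbers. With a single group there was no test between groups and no pairing of samples across groups, and sequencing depth has no counterpart in these data; the precision is set by the 3 repeats and the cycle number.

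The level of a target was the Ct of ACTB minus the Ct of the target in the same repeat, in log2, and percent of ACTB was taken from the mean of these, assuming an amplification factor of 2. A target was detected if its Ct was under 35 in all 3 repeats. For ranking only, an absent Ct was set to 40. When levels of the normalized table were ranked, targets marked ND were set to the matching level, -24.95 log2. Roles (98 ligands, 78 receptors, 2 others, ACTB as reference) were assigned from the file's descriptions and textbook knowledge after the files were seen. Of the symbols, 174 were used as listed and 5 matched through another symbol, with a RefSeq gene table of GRCh38.p14 used for names. For 6 targets (IL2, IL2R, PROK1, PRKAR1A, FGFR2, WNT3) the listed primer name pointed to another gene or was shared, and counts were repeated without them.

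The design was fixed at the same stage as the alternatives below: 32 gene lists, of which 25 had at least 3 measured targets and were tested, and 129 ligand and receptor pairs, of which 75 were on the panel. The genes to be named were also fixed then: the 10 detected ligands and 10 detected receptors with the highest level, both members of every VEGF, angiopoietin, IL-1, IL-6, CXCL8 and CXCL12 pair, the 3 detected targets with the largest SD, up to 4 members of each list that passed, and the reference gene. Detected shares were compared with Fisher's exact test, and levels of classes and lists with an exact rank-sum permutation test that counts all assignments, with ties at midranks; both were two-sided. Benjamini-Hochberg adjustment was at 0.05. Pair differences were tested with limma (lmFit and eBayes), since a sign-flip permutation test of a single pair with 3 repeats cannot go below 0.25. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

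Both tests were tested on simulated data. For the rank-sum test on the 178 targets, 6.5% of 200 random lists of 10 passed an unadjusted 0.05, and 71% of 100 lists shifted by 5 log2 were recovered. For limma on the 53 pairs, 84.6% of 26 pairs with a true difference of 3 log2 were recovered, with the right sign in 100%, and 0% of the unchanged pairs were called.

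Alternatives chosen before the data were examined were Ct limits of 33 and 38, detection in 2 repeats, leaving out each repeat, the median of detected targets as the reference, a factor of 1.9 per cycle, absent Cts left out, detected targets only, a pooled residual in the pair test, and the deposited normalized table as the source of levels. Detection by the deposited normalized table (a value above 9.90e-05% of ACTB in all repeats, or any listed value) or by both tables, the counts without the 6 doubtful primers, and the comparison of spread between ligands and receptors were chosen after seeing the data. The 9.90e-05% is the level of a Ct of 35 at the ACTB Ct of the Ct table. The ACTB Ct behind the normalized values is not known, so for them the limit need not equal a Ct of 35. Genome coordinates are not given, since the files name no build.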

Results

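Transcripts of 178 cytokines, chemokines, growth factors, hormones, their receptors and a few related genes were measured by SYBR Green quantitative RT-PCR in ZR-75, an established human breast cancer line. The labels describe the line as a ductal carcinoma positive for the oestrogen, progesterone and HER2 receptors. There was a single group, untreated ZR-75 cells with 3 repeats, so no condition was compared with another. Per the series' design text, the purpose was to screen ligands and their receptors linked to tumour vessels and metastasis for candidate autocrine and paracrine mediators; the other lines and normal breast material it mentions were not analysed here. The labels do not say whether the repeats, here called A, B and C after their columns, were separate cultures. The limma p-values of the pairs therefore measure only the spread between these samples, which may be technical. All other p-values come from tests over targets, which are not independent replicates, and do not measure that spread. Levels below are log2 values relative to beta-actin (ACTB, mean Ct 15.1) from the deposited Ct table, given as mean ± SD (n = 3) with the geometric mean as percent of ACTB. The authors also deposited a normalized table, and it does not follow from the Ct table. Statements below are about the Ct table unless the normalized one is named; values of the normalized table are given beside many of them, and the tables are compared at the end.

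Most of the panel gave a signal in ZR-75 cells. A Ct under 35 in all 3 repeats, called detected here, was found for 145 of 178 targets, or 81.5% (exact 95% binomial interval over targets, 74.96 to 86.9%), and 127 were detected in both tables. Values of controls without template or reverse transcriptase were not used here, so a late Ct is not by itself proof of a transcript. Melting-curve results were not used either, so the identity of the product was not checked at any Ct, early ones included. The detected targets included 78 of 98 ligands (79.6%, 70.3 to 87.1%) and 65 of 78 receptors (83.3%, 73.2 to 90.8%). No Ct was listed in any repeat for 25 targets, 16 ligands and 9 receptors. Among them was the stem cell factor receptor KIT, marked ND in the deposited normalized table too. The alarmin IL33, its receptor IL1RL1 and FSHR, the receptor of follicle-stimulating hormone, had no Ct but were listed in the normalized table at 0.00534%, 0.00165% and 0.00103% of ACTB. The detected share was 3.74 percentage points lower in ligands than in receptors, which Fisher's exact test did not separate (two-sided p = 0.565). In the deposited normalized table the gap depended on the limit. It was -24.2 points (Fisher's exact p = 4.73e-05) for values above 9.90e-05% of ACTB in all repeats, the level of a Ct of 35 in the Ct table. For any listed value, 85 of 98 ligands and 74 of 78 receptors, it was -8.14 points (Fisher's exact p = 0.0778). For detection in both tables with the limit of 9.90e-05% it was -17.5 points (Fisher's exact p = 0.0124). Whether that limit equals a Ct of 35 behind the normalized values is not known. These alternatives were chosen after seeing the data.

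A small set of transcripts was abundant and most were scarce. Among the 145 detected targets 16 reached 1% of ACTB, 30 lay from 0.1 to under 1%, 26 from 0.01 to under 0.1%, and 73 under 0.01%. The median was -13.34 log2, or 0.00962% of ACTB (interquartile range -15.52 to -9.23 log2). The 2 highest ligands were macrophage migration inhibitory factor, MIF, at -3.34 ± 0.07 log2 (9.88% of ACTB) and FSHB, the beta chain of follicle-stimulating hormone, at -3.40 ± 0.93 (9.45%). Their order was not settled: without repeat A FSHB was at 13.7% and MIF at 10.1%, and the deposited normalized table gave 9.30% and 2.84%. Transforming growth factor beta 1, TGFB1, stood at -4.39 ± 1.56 (4.78%, or 8.69% without repeat A and 3.02% without C). The activin and inhibin chain INHBB measured 2.56%, IL20 2.31%, the KIT ligand KITLG 1.99%, the gp130 ligands CLCF1 1.74% and LIF 1.38%, and the chemokines CXCL16 1.14% (0.731% without repeat C) and CCL28 1.05%. The highest receptor was LTBR, the lymphotoxin beta receptor, at -3.20 ± 0.02 (10.9%). The interleukin-1 receptor IL1R1 stood at -3.91 ± 0.19 (6.64%) and the TNF receptor TNFRSF1A at -5.26 ± 0.03 (2.60%). The prolactin receptor PRLR measured 1.56%, TGFBR1 1.38%, LIFR 0.779%, BMPR2 0.726%, the growth hormone receptor GHR 0.593%, IL11RA 0.575% and IL17RA 0.438%. The deposited normalized table gave nearly the same level for LTBR (11.4%), FSHB and TGFBR1 (1.43%). It gave far lower ones for INHBB (4.92e-04%, from 2.48e-04 to 0.00135% with a repeat left out), IL17RA (1.89e-04%), IL1R1 (0.0924%), PRLR (0.0510%) and IL20 (0.0466%).

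**Figure D1:**
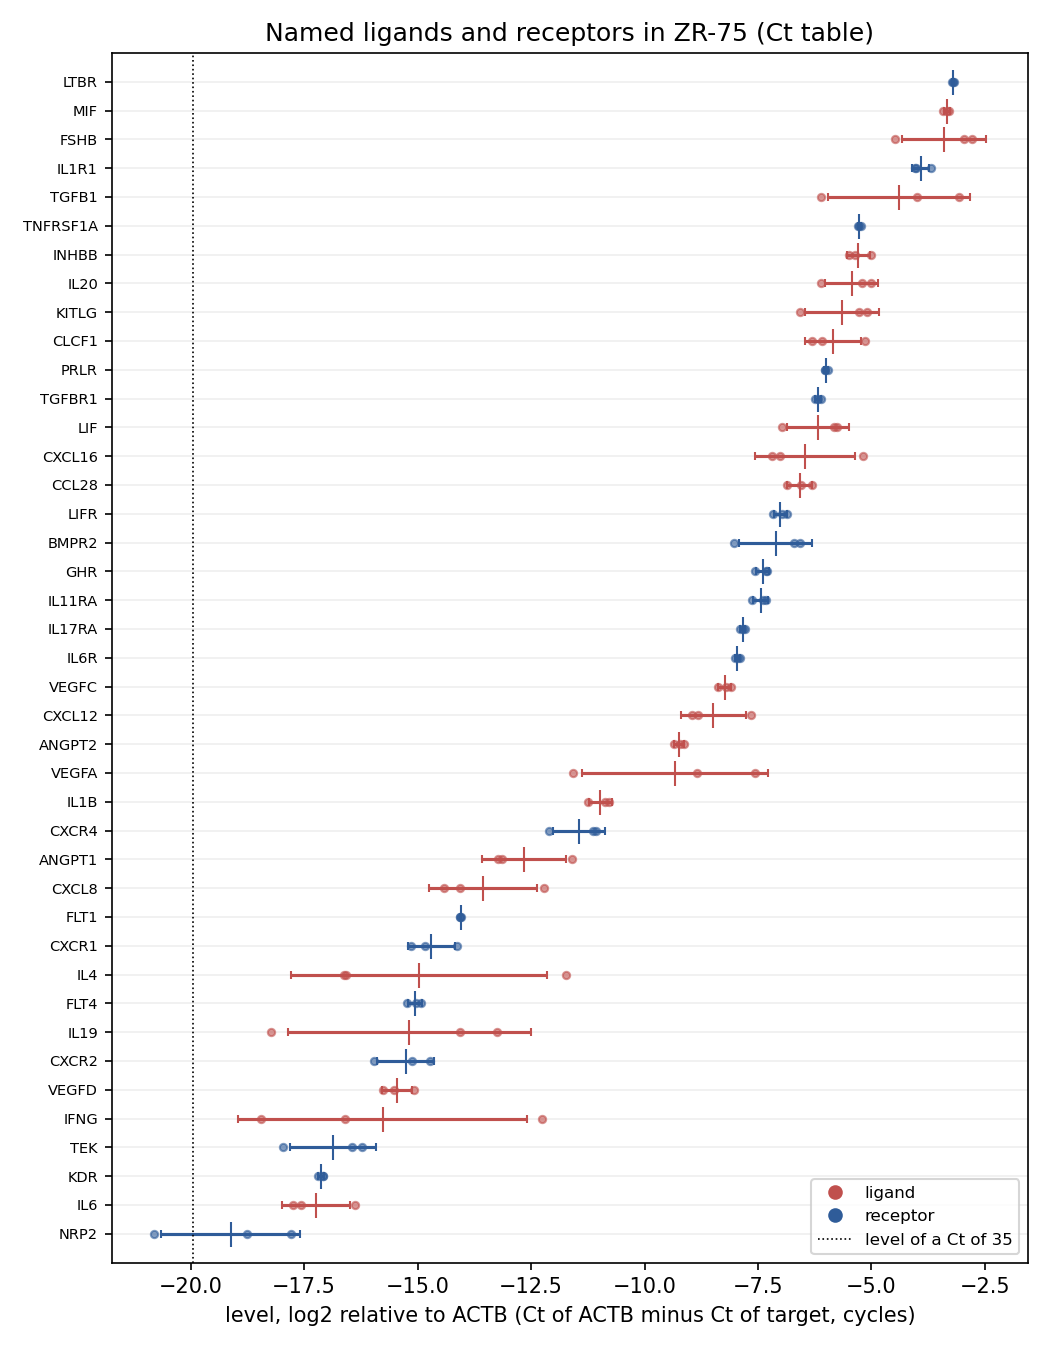
Log2 level relative to ACTB, in cycles, of the named ligands (red) and receptors (blue) in ZR-75 from the Ct table. Points are the 3 repeats, the vertical tick is their mean and the bar 1 SD. LTBR, MIF and FSHB lie furthest to the right, at -3.20, -3.34 and -3.40; NRP2, whose mean Ct was 34.2, lies furthest to the left and was not counted as detected because it passed the limit in 2 repeats only.

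In the Ct table VEGFA, VEGFC and both angiopoietins were more abundant than their detected receptors. In the deposited normalized table VEGFC exceeded FLT4 but not KDR, and VEGFA exceeded neither KDR nor FLT1. Neither angiopoietin was separated from TEK there, with ANGPT2 at 0.0185%, ANGPT1 at 0.00722% (0.0141% without repeat A) and TEK at 0.0182%. All 4 measured VEGF and PDGF ligands were detected and 3 of them exceeded 0.1% of ACTB. The lymphangiogenic factor VEGFC stood at -8.23 ± 0.15 (0.333%) and VEGFA at -9.33 ± 2.05 (0.155%, or 0.0841% without repeat A and 0.339% without C), while VEGFD reached 0.00222%. Of 5 VEGF and PDGF receptors 4 were detected, none at 0.1% or more: FLT1 measured 0.00588%, FLT4 0.00291% and KDR 6.99e-04%. Angiopoietin 2, ANGPT2, stood at -9.23 ± 0.11 (0.166%), ANGPT1 at -12.66 ± 0.92 (0.0155%) and their receptor TEK at -16.87 ± 0.95 (8.33e-04%). The deposited normalized table placed several of these elsewhere, with VEGFA at 0.00688% (0.00315% without repeat A and 0.0122% without C), VEGFD at 1.102%, NRP2 at 1.46%, KDR at 0.556% and FLT1 at 0.263%. VEGFC, at 0.202%, was within 1 log2 of its Ct-derived level.

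In the Ct table few chemokines, and none of the measured chemokine receptors, reached 0.1% of ACTB. Of 18 CC chemokines 13 were detected and 2 exceeded 0.1% of ACTB, CCL28 and CCL22. CCL22 did so through repeat C, with 0.124% over all repeats (SD 2.19 log2) and 0.0516% without C, and it was marked ND in the deposited normalized table. Of 14 CXC, CX3C and XC chemokines 10 were detected, and CXCL16 and CXCL12 exceeded 0.1%. CXCL12 stood at -8.48 ± 0.72 (0.280%), although the deposited normalized table marked it ND; the neutrophil attractant CXCL8 measured -13.57 ± 1.19 (0.00824%), or -14.25 log2 without repeat A. All 7 CC receptors and all 8 CXC, CX3C and XC receptors had a Ct under 35 in every repeat, and none reached 0.1%. By the deposited normalized values 4 CC receptors and 1 CXC receptor reached it, with 5.23% for CXCR6 and 2.29% for CCR1. CXCR4, the receptor of CXCL12, was at -11.44 ± 0.58 (0.0361%), and the CXCL8 receptors CXCR1 and CXCR2 at 0.00375% and 0.00254%.

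Among interleukin families, all 6 measured receptors of the IL-6 and gp130 list were detected, 4 of them at 0.1% or more, with IL6R at -7.95 ± 0.06 (0.403%). The shared chain gp130 itself, IL6ST, was not on the panel. Of the 6 ligands in this family 3 were detected, LIF, CLCF1 and IL6, and IL6 itself was low, at -17.23 ± 0.75 (6.49e-04%). In the IL-1 family IL1B, at -10.97 ± 0.25 (0.0499%), and IL1R1 were detected, while IL33 and IL1RL1 had no Ct. Common gamma chain and type 2 cytokines were detected for 7 of 8 ligands, none at 0.1%, and for 5 of 9 receptors. The common gamma chain itself, IL2RG, was not on the panel. The IL-10 family had 3 of 3 ligands and 2 of 2 receptors detected, the IL-12 and IL-17 group 5 of 5 ligands and 2 of 3 receptors, and IFNGR1, the interferon gamma receptor, was detected at 0.263%. Interferon gamma itself, IFNG, had a Ct under 35 in each repeat but with an SD of 3.18 log2, and was marked ND in the deposited normalized table.

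In the TNF superfamily 5 of 8 ligands and 8 of 10 receptors were detected, and 1 ligand and 3 receptors reached 0.1% of ACTB. All 5 ligands and all 5 receptors of the TGF-beta and BMP lists were detected, 3 and 2 of them at 0.1% or more. Among these, TGFB2 at 0.103% was under it without repeat B (0.0994%) or C (0.0956%). The activin receptor ACVR1B, on the panel but not in that list, was detected at 0.184% (0.418% in the deposited normalized table). The colony-stimulating factor group had 4 of 4 ligands and 2 of 4 receptors detected. The growth factor list had 5 of 5 ligands and 3 of 4 receptors detected, with EGFR at 0.0303% in the Ct table and 0.0284% in the deposited normalized table. As to markers of other cell types, 4 of 4 endothelial and 6 of 8 leukocyte markers were detected in the Ct table, none at 0.1%, and 4 of 4 stromal markers, of which CXCL12 alone exceeded it. The deposited normalized table placed 2 endothelial markers (KDR 0.556%, FLT1 0.263%) and 3 leukocyte markers (IL10RA 38.9%, IL7R 2.61%, CCR5 0.732%) at 0.1% or more. The leukocyte list median lay at -1.24 log2 from the other targets in the Ct table (exact p = 0.0953, adjusted p = 0.553) and at 2.40 in the deposited normalized one (exact p = 0.122, adjusted p = 0.305). Several of these markers also belong to the receptor lists above. No Toll-like receptor or adaptor was on the panel.

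No gene list stood apart from the rest of the panel after adjustment. An exact two-sided rank-sum permutation test over targets called 0 of 25 lists after Benjamini-Hochberg adjustment and 2 at an unadjusted p under 0.05. TGF-beta and BMP receptors had a median 4.12 log2 above the other targets (exact p = 0.0390, adjusted p = 0.488), and the CC chemokine median differed by -2.11 log2 (exact p = 0.0243, adjusted p = 0.488). With absent Cts left out, neither list passed an unadjusted 0.05 (exact p = 0.0841 and 0.112, in the same order). In the deposited normalized table the CC chemokine difference was -5.20 log2 and passed (exact p = 1.23e-05, adjusted p = 3.08e-04). Targets marked ND were set to -24.95 log2 there, and 12 of the 18 CC chemokines were listed against 161 of all 178 targets. How much of the difference rests on that setting was not tested. Median and mean differences had opposite signs for 5 lists: the IL-12 and IL-17 ligands (-0.94 and 0.83) and receptors (3.74 and -0.08), the common gamma chain and type 2 receptors (0.48 and -1.48), the CXC, CX3C and XC chemokines (0.14 and -1.54) and the growth factor ligands (-1.28 and 2.32). Targets are not independent replicates, so these tests describe the panel. Most lists held fewer than 10 targets, and how large a shift the adjusted test could find was not measured. A list that did not pass is therefore not shown to be like the others.

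Ligands as a class were not separated from receptors as a class by level in the Ct table, but were in the deposited normalized table. With absent Cts set to 40, the median was -14.93 log2 for 98 ligands and -14.12 for 78 receptors, a difference of -0.81 (exact two-sided rank-sum permutation p = 0.552). In the deposited normalized table, with targets marked ND set to -24.95 log2, the difference was -4.97 log2 (exact p = 9.80e-07).

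The pairing of ligands with their own receptors bears on the question of autocrine signalling. Of 75 fixed ligand and receptor pairs measured on the panel, both partners were detected in 53, the ligand alone in 6, the receptor alone in 14 and neither in 2. On the whole panel 79.6% of ligands and 83.3% of receptors were detected, so most pairs of any kind would have both partners detected. Whether 53 exceeds the count for unrelated ligands and receptors was not tested. A pair holds a single receptor chain. Further chains such as IL6ST, IL2RG, IL10RB and IFNGR2 were not on the panel, so a detected pair does not show a complete receptor. CCR10, also fixed as a receptor of CCL28, was not on it either. Within-repeat differences between partners passed an adjusted p of 0.05 in limma for 38 of the 53 pairs. The ligand was higher in 19 and the receptor in 19. Levels of detected targets differ widely, with an interquartile range of -15.52 to -9.23 log2. How often unrelated targets would pass was not tested, so the 38 calls are no evidence of a link between partners. When each repeat was left out in turn, 21 of the 38 passed every time with the same sign. Some of these 21 were not tested in the deposited normalized table, where a partner was marked ND or did not exceed 9.90e-05% of ACTB in every repeat. They were CXCL12 and CXCR4, IGF1 and IGF1R, IL13 and IL13RA2, IL9 and IL9R, and TNF and TNFRSF1A. CXCL12, IL13 and TNF were marked ND there, while IGF1 and IL9 were listed in all repeats and left out by the limit alone. Among the rest of the 21, 9 passed in the deposited normalized table with the same sign as in the Ct table. The ligand was higher in 4 of them and the receptor in 5. The ligand was higher in the pairs MIF and CD74 (14.77 ± 0.53 log2, SE, n = 3; limma adjusted p = 1.58e-04), CCL28 and CCR3 (10.76 ± 0.68), TNFSF13B and TNFRSF13C (7.50 ± 0.43), and VEGFC and FLT4 (6.84 ± 0.37). The receptor was higher in LTB and LTBR (-9.87 ± 0.35), IL6 and IL6R (-9.28 ± 0.46), IL1B and IL1R1 (-7.06 ± 0.36), CXCL11 and CXCR3 (-3.57 ± 0.35), and CXCL10 and CXCR3 (-2.18 ± 0.35). Their sizes depended on the table: in the deposited normalized one the differences were 1.45, 3.10, 1.46 and 9.21 log2 for the ligand-higher pairs and -13.73, -8.62, -3.05, -3.88 and -4.85 for the receptor-higher pairs, in the same order. Pairs outside the VEGF, angiopoietin, IL-1, IL-6, CXCL8 and CXCL12 groups are named here after their values were seen.

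Other angiogenic pairs were called in the Ct table but were reversed or not called in the deposited normalized table. VEGFC exceeded KDR by 8.90 ± 0.36 log2 (SE, n = 3; limma adjusted p = 1.67e-04), VEGFA exceeded KDR by 7.80 ± 0.87 and FLT1 by 4.72 ± 0.88, and ANGPT2 and ANGPT1 exceeded TEK by 7.64 ± 0.54 and 4.22 ± 0.47. In the deposited normalized table the differences were -1.46, -6.34, -5.26, 0.03 and -1.33, in the same order. The VEGFC and VEGFA differences passed there with the opposite sign (limma adjusted p = 0.0144, 0.00312 and 0.00693). The angiopoietin differences did not pass there (limma adjusted p = 0.959 and 0.203). In the Ct table the VEGFA calls did not pass on the 2 repeats left without B. The differences were then 7.58 log2 against KDR (limma adjusted p = 0.0628) and 4.48 against FLT1 (limma adjusted p = 0.132), sizes close to those from all repeats. CXCL12 exceeded CXCR4 by 2.96 ± 0.42 log2 (limma adjusted p = 0.00404), a pair the deposited normalized table cannot give because CXCL12 is marked ND there. VEGFD and FLT4 (-0.39 ± 0.36, limma adjusted p = 0.356), CXCL8 and CXCR1 (1.14 ± 0.71, 0.210) and CXCL8 and CXCR2 (1.70 ± 0.57, 0.0520) did not pass. The number of calls was 24 without repeat B, against 35 without A and 41 without C. Different primers can amplify with different efficiency, which was not given in the sources used here, so a difference between 2 transcripts carries that unknown.

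**Figure D2:**
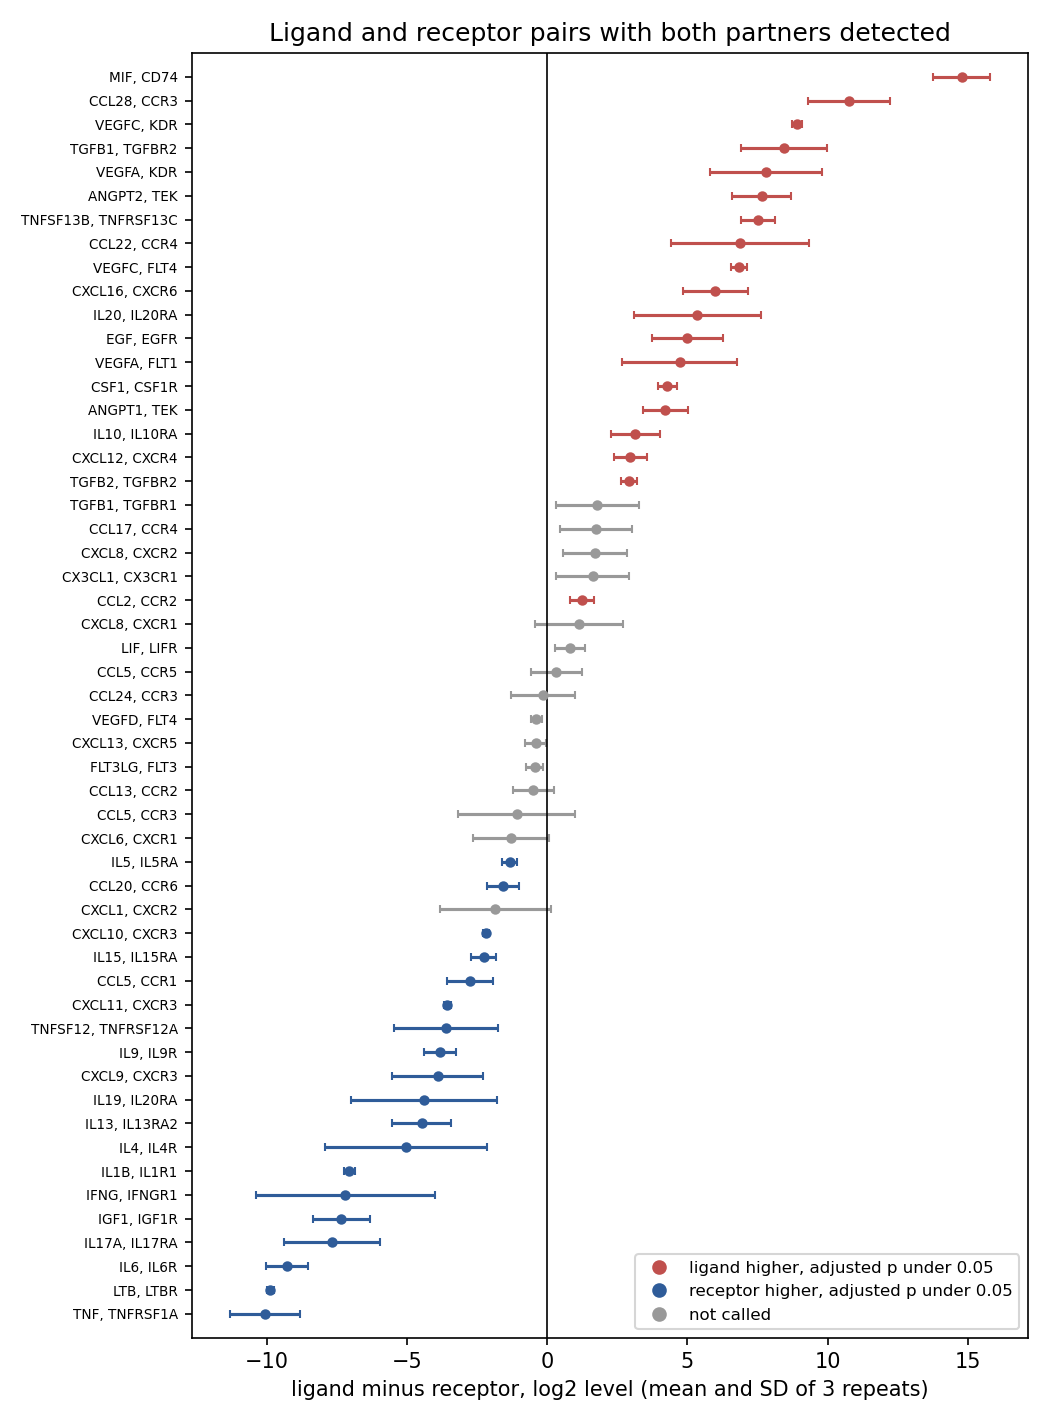
Ligand minus receptor difference in log2 level for the 53 pairs with both partners detected in the Ct table; points are means of the 3 repeats and bars 1 SD. Red and blue mark the 38 pairs that passed limma at an adjusted p of 0.05 with the ligand or the receptor higher, and grey the others; the range runs from MIF and CD74 at 14.77 to TNF and TNFRSF1A at -10.05.

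The median SD between repeats over the 145 detected targets was 0.46 log2, and it was 0.717 for ligands and 0.242 for receptors. Between A and B 85 targets lay within 0.5 cycles, between A and C 70 and between B and C 82. Across targets, which are not independent replicates, Pearson's r of Ct was 0.978 between A and B, 0.933 between A and C and 0.937 between B and C. The median Ct difference was 0.03, 0.19 and 0.08 cycles for these comparisons, and 9, 29 and 21 targets differed by over 2 cycles. The widest SDs were those of IFNG (3.18 log2), IL4 (2.82) and IL19 (2.67), all under 0.01% of ACTB.

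The 2 deposited tables gave different levels for most targets. Over the 143 targets with values in all repeats of both, the log2 levels correlated across targets with Pearson's r = 0.416 and Spearman's rho = 0.368. The permutation p was 1e-05 for each, also after adjustment over both, the smallest that 100000 resamples can give. Within ligands r was 0.603 (rho 0.590) and within receptors 0.233 (rho 0.204); the difference between these was not tested. The median absolute difference was 2.70 log2; 30 targets lay within 1 log2, 69 differed by over 3 and 16 by over 8. Ligands were mostly lower in the normalized table, by a median difference of -2.08 log2 over 74 of which 16 were higher, and receptors mostly higher, by 1.40 over 67 of which 47 were higher (exact two-sided rank-sum permutation p = 4.61e-08). The 10 highest ligands of the tables had 4 in common, MIF, FSHB, TGFB1 and CLCF1, where chance gives 1.02. The 10 highest receptors had 4 in common, LTBR, TNFRSF1A, TGFBR1 and BMPR2, where chance gives 1.28.

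**Figure D3:**
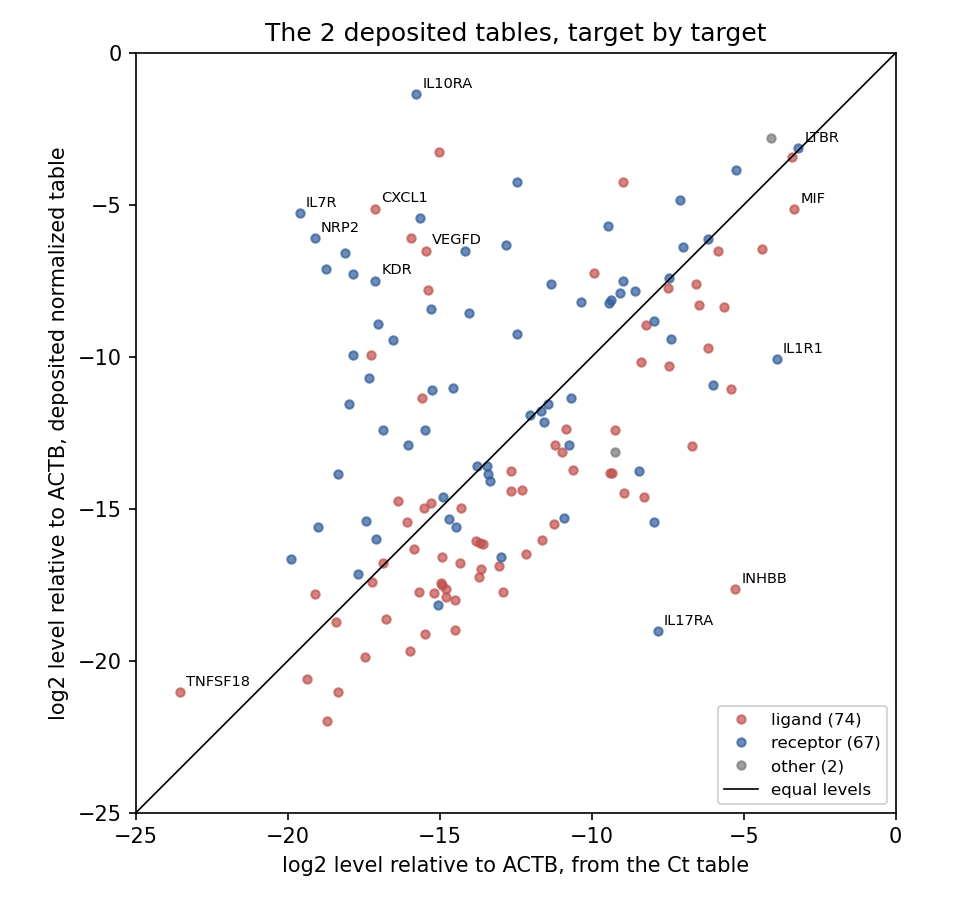
Mean log2 level relative to ACTB of each target from the Ct table (horizontal) and from the deposited normalized table (vertical), for 74 ligands (red), 67 receptors (blue) and 2 other targets (grey); the line marks equal levels. LTBR lies on the line, IL10RA lies above it (difference 14.42 log2) and INHBB below it (difference -12.35 log2).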

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

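With the deposited normalized values the ligand-receptor gap became -24.2 points in detected share above 9.90e-05% of ACTB (p = 4.73e-05, Fisher's exact test), -8.14 points counting any listed value (Fisher's exact p = 0.0778), and -4.97 log2 in level (exact p = 9.80e-07), 1 list passed in place of 0, and the median level was -12.40 log2. Detection in both tables, chosen after seeing the data, gave -17.5 points (Fisher's exact p = 0.0124). The median level was -0.21 log2 with the median of detected targets as reference and -12.36 with a factor of 1.9 per cycle, by construction of the scale. The count of detected targets ranged from 125 to 152 over the Ct limits, was 143 of 178 in the deposited normalized table with that limit and 161 by listing alone, and 143 of 172 without the 6 doubtful primers. Pair calls numbered 39 with a pooled residual and 34 of 43 pairs in the deposited normalized table, 11 with the ligand and 23 with the receptor higher; of 25 Ct-table calls present there, 13 passed with the same sign and 7 with the other.

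Leaving out each repeat gave 145 to 149 detected targets, 53 to 56 pairs with both partners detected, gaps of -6.57 to -2.72 points and -0.98 to -0.57 log2 between ligands and receptors, median levels of -13.47 to -13.14 log2, 0 passing lists each time, and 24 to 41 called pairs. The lowest count, 24, came without repeat B; it rests on A and C, which differed by over 2 cycles for 29 targets.

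Of 36 pairs tested in both tables, 21 had the opposite sign in the deposited normalized table, and the cause was not tested. There the ligand minus receptor difference was -1.33 log2 for ANGPT1 and TEK, 6.84 for CCL13 and CCR2, -8.47 for CCL17 and CCR4, -2.36 for CCL2 and CCR2, -0.49 for CSF1 and CSF1R, -4.03 for CXCL16 and CXCR6, 5.97 for CXCL1 and CXCR2, -5.06 for CXCL8 and CXCR2, -1.14 for EGF and EGFR, 5.26 for FLT3LG and FLT3, -13.04 for IL10 and IL10RA, -3.33 for LIF and LIFR, -0.15 for TGFB1 and TGFBR2, -0.95 for TGFB2 and TGFBR2, -5.26 for VEGFA and FLT1, -6.34 for VEGFA and KDR, -1.46 for VEGFC and KDR, and 11.66 for VEGFD and FLT4. It was -2.90 for CX3CL1 and CX3CR1, -0.80 for CXCL8 and CXCR1 and -0.32 for TGFB1 and TGFBR1, which passed in neither table. Of the 21, 7 passed in both tables with opposite signs. They were CCL2 and CCR2, CXCL16 and CXCR6, EGF and EGFR, IL10 and IL10RA, VEGFA and FLT1, VEGFA and KDR, and VEGFC and KDR. The others did not pass in both tables, so a reversal is not shown for them. At 3 repeats, differences near the median SD of 0.46 log2 are not resolved.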

Other observations

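All tests of explanations in this part were chosen after the results were seen, except that of the spread in the deposited normalized table, which was written down before that value was computed.

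A set of 30 targets, 12 ligands and 18 receptors, had levels within 1 log2 in both deposited tables. At the top were LTBR (10.9% of ACTB by Ct, 11.4% by the deposited normalized table) and FSHB (9.45% and 9.30%), followed by CLCF1 (1.74% and 1.102%), TGFBR1 (1.38% and 1.43%) and LIFR (0.779% and 1.19%). Endothelin 1, EDN1, a vasoconstrictor peptide, measured 0.551% and 0.474% with wide spread (0.939% by Ct without repeat A), IL6R 0.403% and 0.223%, VEGFC 0.333% and 0.202%, and IFNGR1 0.263% and 0.443%. Receptors of intermediate level in both were CXCR4 (0.0361% and 0.0334%), EGFR (0.0303% and 0.0284%) and IGF1R (0.0240% and 0.0256%). IL6 (6.49e-04% and 5.68e-04%) and CCL5 (2.84e-04% and 2.28e-04%) were low in both. With a repeat left out, the deposited values ran from 0.855 to 1.73% for CLCF1, from 0.326 to 0.965% for EDN1 and from 1.04e-04 to 4.13e-04% for CCL5. These targets were picked because they were alike, after their values were seen. How many of the 143 would lie within 1 log2 by chance was not computed. The repeat-to-repeat deviations of these 30 correlated between the tables at r = -0.212, against 0.212 for the other 113 targets. The closeness of their levels is therefore not shown to be more than coincidence.

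At the other end, 16 targets differed by over 8 log2. Higher in the deposited normalized table were IL10RA (0.00177% by Ct, 38.9% deposited), IL7R (1.25e-04% and 2.61%), NRP2 (1.75e-04%, or 3.14e-04% without repeat A and 1.10e-04% without B, and 1.46%), the activin chain INHBA (0.00302% and 10.4%) and CD74 (3.53e-04% and 1.04%). INHBB and IL17RA were lower there. CXCL12 and CCL22, with mean Cts of 23.5 and 24.7, were marked ND in the deposited normalized table, and CXCL3, with no Ct, was listed there at 0.755%. The 25 targets without a Ct and the 17 marked ND in the normalized values had 7 in common, where chance gives 2.39 (Fisher's exact p = 0.00351).

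The first pattern weighed is this disagreement between tables. Another reference or scale would leave a residual around a single line no larger than the repeats' own spread, but the residual SD was 9.06 times the median SD between repeats. Rows out of order would keep each row's repeat-to-repeat steps: at most 25 of 161 rows matched any Ct row within 0.02 cycles when a constant was allowed per step (23 with the signs turned), and 18 without it (9 with the signs turned). The bound of fewer than a majority of rows was set after these excesses over the sign-turned matches were seen, so a few misplaced rows are not excluded. The same reactions read at another threshold would share repeat deviations, yet the highest correlation over the 6 column orders was 0.137. Values of another sample or another run in either table may account for a median absolute difference of 2.70 log2 and cannot be told apart from each other, since no second sample is at hand; no biological explanation was tested, as the design has a single group.

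The second pattern is that ligands varied more between repeats than receptors. The median SD was 0.717 log2 over 78 detected ligands and 0.242 over 65 receptors, a ratio of 2.96 (exact two-sided rank-sum permutation p = 9.81e-08), and repeat C came over 1.5 cycles earlier than both others for 17 ligands and 0 receptors. Low template alone is argued against by a ratio of 5.34 among targets with a mean Ct under 25 (exact p = 2.45e-06); it was 2.24 from 25 to under 30 (exact p = 8.44e-04) and 1.59 above (exact p = 0.0612). Without C the ligand median SD was 0.357 log2 and the receptor one 0.156. Without A they were 0.445 and 0.170, and without B 0.856 and 0.191. These SDs rest on 2 repeats and are not on a par with those over 3, so they do not assign the ligand spread to repeat C alone. As the whole cause a single repeat out of line is argued against by the ratios with a repeat left out. These ran from 2.30 to 4.48 (lowest without C, highest without B). A feature of the Ct table alone is argued against by a ratio of 3.39 in the deposited normalized table (exact p = 1.33e-10). That ratio was not taken at matched levels, and ligands as a class lay lower there. It therefore cannot show that the spread has the same source in both tables. Ligand and receptor panels may have been run on different plates, days or cDNA preparations, which the labels do not record, so this stays open; no biological explanation was tested.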
